A study of Mus musculus with 36 samples.

How the data were processed

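Distal colon RNA of 36 mice was measured on Affymetrix arrays, 1 array per animal: 9 Control, 7 scrambled siRNA, 6 siTNF, 6 siTNF-OMe and 8 siTNF-OMe-P. Per the labels, total RNA was isolated with RNeasy, amplified as whole transcriptome from 25 ng and biotin labelled, in 3 amplification and 2 hybridization batches. The deposited values are log2 probe set signals that the authors made with Partek and RMA, with no versions given; whether batch effects were removed is not given in the sources used here. RMA usually gives arrays the same spread, but the array SDs ran from 1.55 to 1.89. MPO activity, colon length, colon weight and their ratio come from the labels, where MPO is in units of peroxide breakdown per mg.

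No probe set was filtered out. Of 28853 probe sets, 21789 carry 1 gene, 1621 several and 5443 none in the platform annotation (19938 genes), 476 hold the same values as an earlier one, and no 2 arrays were identical. Gene positions come from a reference annotation of GRCm38. Signal over background is not given in the sources used here. The median SE of scrambled over Control was 0.108 log2, which with 36 arrays and 28 residual degrees of freedom sets the precision. The first principal component held 48.8% of the variance and had r = -0.969 with array SD, and the second held 19.4%.

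Probe sets were compared with limma 3.58.1 in R 4.3.3 by a linear model of group, amplification batch and hybridization batch on all arrays, with empirical Bayes moderation and a mean-variance trend. Tests were two-sided with Benjamini-Hochberg adjustment over probe sets in each of 10 comparisons and a threshold of 0.05. No probe set passed for the batch terms. The first 7 comparisons also tested 37 fixed gene lists (702 genes, 734 of 804 list places measured) with camera at a preset correlation of 0.01, adjusted over 259 tests, with an estimated correlation and with fry. MPO activity, length and ratio were compared by exact two-sided permutation of group labels, adjusted over 30 tests, and list scores were related to MPO by 100000 two-sided permutations over 35 lists. The slope of each TNF siRNA difference on the scrambled-to-Control difference used 70 splits of the scrambled arrays, so that no scrambled array entered both. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

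The groups, comparisons, lists, tests, most alternatives and the rule for naming genes were set before the data were examined. The rule names Tnf, the 10 highest and 10 lowest called genes of a comparison, and up to 2 risen and 2 fallen called members per list; where fewer than 20 genes pass it names the 5 smallest p values. Shifted lists may add up to 4 members. For the comparisons among siRNA groups the members were narrowed, after values were seen, to 2 from each of the 5 lists of smallest p. The limit of 1.7 on array SD, array SD as a covariate, the fits without Control, list means with 1 array left out and the mean of 8 for squamous markers were also chosen after seeing the data.

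The alternatives were no or single batch terms, each batch alone, only the 2 groups compared, the replicate number as a block in place of the batch terms, 11541 dim probe sets left out (the lowest 40% by mean), quantile normalization, median centring, moderation without trend or robust, array weights (0.059 to 5.49), a log2 minimum of 0.5 or 1, 1 probe set per gene, each array left out in turn, and for the colon measures medians, log2 and a recomputed ratio. Named genes other than Tnf were recomputed within hybridization but not within amplification batches. The fit was tested on simulated data: for siTNF-OMe-P over scrambled it recovered 55.5, 93.4 and 99.7% of changes of 0.5, 1 and 2 log2 with 0% false calls, and for scrambled over Control 23.4% of calls were false. Camera with the preset called 48.9 and 39.4% of unshifted lists there, with an estimated correlation 0 and 2.78%, and fry 0. Planted slopes of 0, -0.3 and -0.6 were recovered as 0.0049, -0.302 and -0.590.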

Results

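Gene expression was measured in the distal colon of 36 mice with 1 Affymetrix array per animal. The mice were 9 labelled Control, 7 given a scrambled siRNA, 6 given an unmodified siRNA against Tnf (siTNF), 6 given one with O-methyl nucleotides (siTNF-OMe) and 8 given one carrying O-methyl-propanediol (siTNF-OMe-P). Tnf encodes tumour necrosis factor, a cytokine that drives inflammation, and the siRNAs were given intrarectally. The labels give 5% dextran sulfate sodium (DSS), a compound that injures the colon epithelium, as the treatment of all 36 animals, Control included. The design text of the series names only the siRNA-dosed groups, so what the Control animals received is not settled here and Control is used as a name. Each array held 28853 probe sets on a log2 scale that ran from 4.95 to 14.1, and the lowest correlation between 2 arrays was 0.852. The number of arrays limits the precision of every value.

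The scrambled group had higher inflammation measures than Control. Myeloperoxidase (MPO) activity, an enzyme activity carried by neutrophils, was 0.583 ± 0.440 U per mg (SD, n = 7) against 0.0380 ± 0.0279 (n = 9), a difference of 0.545 (95% interval 0.277 to 0.859, exact permutation adjusted p = 6.56e-04). The colon was shorter, at 6.07 ± 0.304 against 7.68 ± 0.273, a difference of -1.61 (-1.90 to -1.30, exact permutation adjusted p = 6.56e-04, n = 7 and 9). Its weight to length ratio was higher, at 2.76 ± 0.225 against 2.18 ± 0.130 mg per mm, a difference of 0.584 (0.390 to 0.780, exact permutation adjusted p = 6.56e-04). For each of the 3 measures all 7 scrambled animals lay beyond all 9 Control animals, and the unadjusted exact p of 8.74e-05 is the smallest these group sizes can give. Colon weight alone was 166 ± 13.9 mg in scrambled and 167 ± 13.7 mg in Control. Colon length is labelled in mm, but the labelled ratio equals weight over 10 times length, as it would for cm, so lengths are given as labelled.

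Among the siRNA-dosed groups, the animals given siTNF-OMe-P had the lowest weight to length ratio, 2.56 ± 0.215 mg per mm (SD, n = 8), against 2.85 ± 0.164 for siTNF and 2.88 ± 0.103 for siTNF-OMe (n = 6 each). The ratio was lower with siTNF-OMe-P than with siTNF-OMe by a difference of -0.325 (-0.535 to -0.126, exact permutation adjusted p = 0.00845), with 8 of 8 animals below the siTNF-OMe mean. Against siTNF the difference was -0.294 (-0.529 to -0.0699, exact permutation adjusted p = 0.0250), again with 8 of 8 animals below the mean of the other group. That second call was lost with medians (-0.213, exact permutation adjusted p = 0.0564), with a ratio recomputed from weight and length (-0.271, 0.0557), without siTNF replicate 3 (-0.245) and without siTNF replicate 6 (-0.265). In 3 animals the labelled ratio differed from weight over length by more than a tolerance of 0.015: scrambled replicate 7 (2.76 against 2.59), siTNF-OMe replicate 1 (2.82 against 2.80) and siTNF-OMe-P replicate 3 (2.62 against 2.79).

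MPO activity and colon length did not pass between any 2 siRNA-dosed groups. Mean MPO activity was 0.302 ± 0.232 U per mg for siTNF, 0.606 ± 0.376 for siTNF-OMe and 0.342 ± 0.270 for siTNF-OMe-P (SD, n = 6, 6 and 8). Against scrambled, MPO differed by -0.281 (-0.739 to 0.141) for siTNF, by 0.0224 (-0.493 to 0.528) for siTNF-OMe and by -0.241 (-0.645 to 0.146) for siTNF-OMe-P, with exact permutation adjusted p values of 0.294, 0.919 and 0.301. Between the TNF siRNAs, MPO differed by 0.303 (-0.101 to 0.722) for siTNF-OMe over siTNF, 0.0401 (-0.260 to 0.328) for siTNF-OMe-P over siTNF and -0.263 (-0.633 to 0.113) for siTNF-OMe-P over siTNF-OMe. Mean colon length was 5.83 ± 0.501 for siTNF, 5.93 ± 0.281 for siTNF-OMe and 6.36 ± 0.358 for siTNF-OMe-P. The largest length difference, siTNF-OMe-P over siTNF, was 0.529 (0.0250 to 1.04) with an exact permutation adjusted p of 0.0768; siTNF-OMe-P exceeded siTNF-OMe by 0.429 (0.05 to 0.820) with 0.0566. Against scrambled, colon length differed by -0.238 (-0.747 to 0.267), -0.138 (-0.500 to 0.204) and 0.291 (-0.0864 to 0.667) for siTNF, siTNF-OMe and siTNF-OMe-P, and the ratio by 0.0912 (-0.162 to 0.344), 0.121 (-0.111 to 0.354) and -0.203 (-0.452 to 0.0400). Between siTNF-OMe and siTNF the length differed by 0.1 (-0.433 to 0.633) and the ratio by 0.0303 (-0.149 to 0.209). For the length difference of siTNF-OMe-P over siTNF-OMe, a test with random permutations within hybridization batches gave an adjusted p of 0.0498, too close to 0.05 to tell from it. This length difference passed without siTNF-OMe-P replicate 3 (0.467, 0.0478), siTNF-OMe-P replicate 6 (0.481, 0.0291) or siTNF-OMe-P replicate 8 (0.467, 0.0478), where values are the difference and its exact permutation adjusted p. That over siTNF passed without siTNF replicate 4 (0.642, 0.0311), and that over scrambled without scrambled replicate 3 (0.396, 0.0320).

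**Figure D1:**
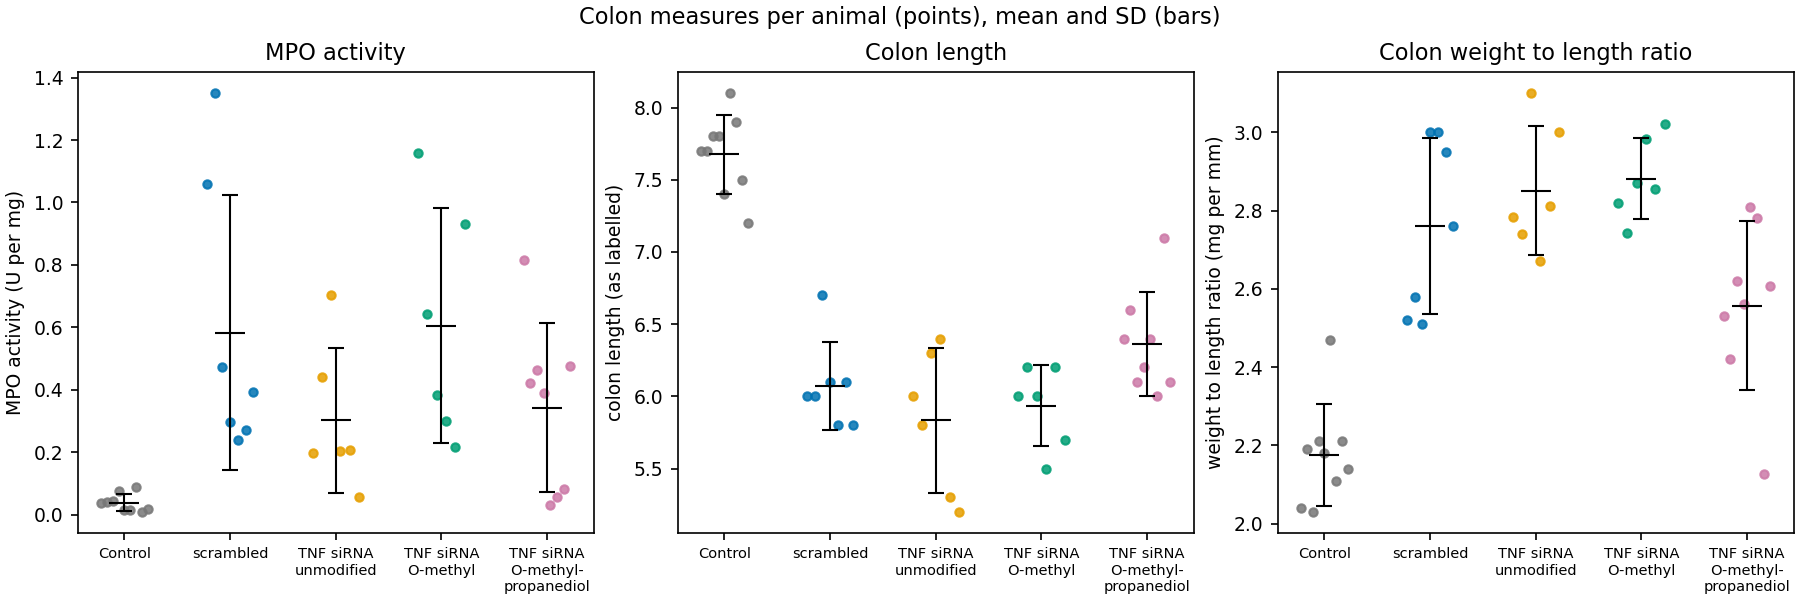
MPO activity (U per mg), colon length (as labelled) and weight to length ratio (mg per mm) of each animal in the 5 groups, with points for animals and bars for the mean and SD. The 9 Control animals lie at an MPO activity of 0.088 or less, and the 7 scrambled animals at 0.238 or more.

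The comparison of scrambled with Control gives the difference between an siRNA-dosed colon with no Tnf-directed sequence and the Control colon. Clca4b, a member of the family of calcium-activated chloride channel regulators, rose 22.7-fold (4.502 ± 0.22 log2, SE, n = 7 and 9, limma adjusted p = 1.14e-15), and the chemokine gene Ccl8 rose 11.7-fold (3.55 ± 0.19). Saa3, an acute-phase protein gene, rose 8.41-fold (3.07 ± 0.45), and Tac1, which encodes the neuropeptide substance P, rose 8.08-fold (3.02 ± 0.28). Reg4, a lectin gene of secretory epithelial cells, was 8.03-fold lower (fell by 3.00 ± 0.13 log2, limma adjusted p = 9.19e-17).

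The rest of the 10 genes with the highest changes were Wfdc17 (2.63 ± 0.14), Hp (2.58 ± 0.37), which encodes the haemoglobin scavenger haptoglobin, Lcn2 (2.53 ± 0.32), an iron-sequestering antibacterial protein, Serpina3n (2.44 ± 0.18), a protease inhibitor, Iigp1 (2.43 ± 0.38), an interferon-inducible GTPase, and Gpnmb (2.32 ± 0.15). Of the genes with the lowest values, Nxpe2 fell by 2.69 ± 0.16, Smpx by 2.30 ± 0.21, Cldn2, a pore-forming claudin of tight junctions, by 2.19 ± 0.13, Cftr, a chloride channel, by 2.03 ± 0.21 and Nox1, an epithelial NADPH oxidase, by 1.84 ± 0.17. Aadac fell by 1.695 ± 0.22, Dio1, a deiodinase of thyroid hormone, by 1.61 ± 0.30, Acer1, a ceramidase, by 1.49 ± 0.19 and Top2a, a topoisomerase of dividing cells, by 1.46 ± 0.22. On the mouse assembly GRCm38 of the reference annotation, Clca4b lies on chromosome 3 from 144910921 to 144932529, Ccl8 on chromosome 11 from 82115185 to 82116799 and Reg4 on chromosome 3 from 98222138 to 98236748. The build behind the array's probes is not given in the sources used here.

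Over all probe sets, limma called 3384 at an adjusted p under 0.05, of which 2099 rose and 1285 fell, and 315 of these changed by at least 1 log2 (223 up and 92 down). They stand for 2659 named genes. At an unadjusted p under 0.05 there were 5934 probe sets, where 1442.6 are expected by chance. Of the 126 called genes that the naming rule gave for this comparison, 94 rose and 32 fell, and in 122 of them all 7 scrambled arrays lay beyond the Control mean, which choosing called genes favours. In 86 of the 126 the arrays of the 2 groups did not overlap, and in the others, Tnf among them, they did. The standard deviation of values within an array was under 1.7 in 8 of the 36 arrays, 4 of them Control, 1 scrambled, 1 siTNF and 2 siTNF-OMe-P, so narrow arrays were most frequent in Control. Without those 8 arrays, a choice made after seeing the data, 14417 probe sets were called, and 2717 of the 3384 kept their direction and threshold. Within the hybridization batches 1031 and 1048 probe sets were called, and 899 and 1038 of the 3384 kept the threshold, all in the same direction. There 49 and 29 of the 126 genes lost their call. With only the 2 groups compared 1714 of the 3384 kept it. Most calls fell within hybridization batch 1 (439 up and 592 down) and amplification batch 1 (392 up and 789 down). Within the amplification batches 597, 1963 and 54 of the 3384 kept direction and threshold, with 3298, 3384 and 3382 of the 3384 in the same direction, where groups held 1 to 4 arrays. In data simulated from these arrays with 200 changed probe sets, the same fit recovered 65.1, 91.3 and 100% of changes of 0.5, 1 and 2 log2, and 23.4% of its calls over 5 simulations were false.

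Macrophage genes had the highest median of the 37 gene lists. Counts of list members are of those measured, and p values of a list are for its genes as a set. In the monocyte and macrophage list, 21 of 25 members rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 1.01 log2. Monocyte and macrophage genes gave adjusted p = 5.47e-29 (preset) and adjusted p = 0.0163 with an estimated correlation. The lysosomal marker Cd68 rose by 1.87 ± 0.12, the Fc receptor gene Fcgr3 by 1.68 ± 0.16, Ms4a6d by 2.23 ± 0.17 and Ms4a7 by 1.67 ± 0.15. In the epithelial antimicrobial list, 13 of 24 members rose and 1 fell (14 and 1 adjusted over the list alone). Epithelial antimicrobial genes gave adjusted p = 2.23e-09 (preset) and adjusted p = 0.00182 with an estimated correlation. Duoxa2, the maturation factor of a hydrogen peroxide producing oxidase, rose by 1.80 ± 0.21, the protease inhibitor gene Slpi by 1.26 ± 0.10 and the peptidoglycan receptor gene Pglyrp1 by 0.52 ± 0.060, while Nox1 fell, as given with the lowest genes. These were the 2 lists of the 24 past the preset test that also passed with an estimated correlation, and 20 of the 24 passed fry, whose p tests whether a list's genes move on balance in 1 direction (neutrophil, B and plasma cell, adipocyte and hypoxia and glycolysis did not). Without the 8 narrow arrays 17 of the 24 kept the preset call. Lost there were the lists, with mean log2, B and plasma cell (-0.17), adipocyte (0.34), TNF ligand, receptor and signalling (0.23), nucleic acid sensing (0.20), hypoxia and glycolysis (0.055), endoplasmic reticulum stress (0.13) and wound healing and epithelial repair (0.22). The adipocyte list also lost it with quantile normalization, without dim probe sets and with array SD as a covariate.

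Most genes of the type I interferon list rose. In the type I interferon response list, 26 of 28 members rose and 0 fell (27 and 0 adjusted over the list alone), with a median of 0.89. Zbp1, a sensor of Z-form nucleic acid, rose by 1.91 ± 0.19, Rtp4 by 1.36 ± 0.19, the antiviral tetherin gene Bst2 by 1.17 ± 0.14 and Ifit3 by 1.02 ± 0.13. In the antigen presentation and interferon gamma list, 18 of 21 members rose and 0 fell (19 and 0 adjusted over the list alone). The immunoproteasome genes Psmb8 and Psmb9 rose by 1.39 ± 0.17 and 1.04 ± 0.14, the peptide transporter gene Tap2 by 0.81 ± 0.11 and B2m, the light chain of class I molecules, by 0.70 ± 0.086. In the nucleic acid sensing list, 9 of 16 members rose and 0 fell (10 and 0 adjusted over the list alone). Unc93b1, which carries Toll-like receptors to endosomes, rose by 0.98 ± 0.16, the adaptor gene Myd88 by 0.93 ± 0.18 and Tlr7, a receptor for single-stranded RNA, by 0.50 ± 0.11. In the RNA interference machinery list, 0 of 15 members rose and 0 fell (0 and 0 adjusted over the list alone). These 4 lists, in the order named, gave adjusted p = 2.16e-25, 4.27e-19, 4.22e-06 and 0.991 (preset). With an estimated correlation adjusted p was 0.147, 0.0800, 0.230 and 0.998.

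Among TNF-related and cytokine genes, the TNF and NF-kB target list had a median of 0.58: 16 of 33 members rose and 0 fell (21 and 0 adjusted over the list alone). Vcam1, an adhesion molecule of activated endothelium, rose by 1.43 ± 0.15. In the TNF ligand, receptor and signalling list, 10 of 21 members rose and 0 fell (10 and 0 adjusted over the list alone). Both TNF receptor genes rose, Tnfrsf1a by 1.20 ± 0.18 and Tnfrsf1b by 1.07 ± 0.14, as did the death receptor gene Fas by 0.80 ± 0.14. In the chemokine list, 12 of 31 members rose and 1 fell (15 and 1 adjusted over the list alone). Cxcl16 rose by 1.09 ± 0.12, Ccl5, which attracts T cells, by 1.10 ± 0.19 and Cxcl13, which attracts B cells, by 1.08 ± 0.19. In the cytokine list, 4 of 29 members rose and 0 fell (4 and 0 adjusted over the list alone), with Tgfb1 at 0.50 ± 0.10 and Il1rn, the interleukin 1 receptor antagonist gene, at 0.39 ± 0.10. For prostaglandin and lipid mediator genes, 3 of 15 members rose and 0 fell (3 and 0 adjusted over the list alone), among them Alox5ap, which activates 5-lipoxygenase, by 1.05 ± 0.18 and Pla2g7 by 1.01 ± 0.20. These 5 lists, in the order named, gave adjusted p = 8.88e-12, 3.18e-05, 4.81e-08, 0.229 and 0.166 (preset). With an estimated correlation adjusted p was 0.176, 0.332, 0.147, 0.843 and 0.611.

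Lists of other leukocytes were tested too. In the neutrophil list, 4 of 21 members rose and 0 fell (6 and 0 adjusted over the list alone), with the calprotectin genes S100a8 and S100a9 rising by 2.04 ± 0.45 and 1.78 ± 0.39, Clec4d by 1.05 ± 0.26 and Ly6g by 0.82 ± 0.094. In the B and plasma cell list, 1 of 19 members rose and 7 fell (1 and 8 adjusted over the list alone). The B cell receptor component Cd79a fell by 0.49 ± 0.12, Ms4a1, which encodes the surface marker CD20, by 0.47 ± 0.12 and the coactivator gene Pou2af1 by 0.43 ± 0.11, and the 1 risen member was the chemokine gene Cxcl13 named with the chemokines. In the T and NK cell list, 2 of 23 members rose and 0 fell (2 and 0 adjusted over the list alone). Cd4, a coreceptor of helper T cells, rose by 0.92 ± 0.10 and Thy1 by 0.58 ± 0.13, which lost its call without the 8 narrow arrays (0.27). In the mast cell and eosinophil list, 0 of 15 members rose and 0 fell (0 and 0 adjusted over the list alone). In the red blood cell list, 0 of 2 members rose and 0 fell (0 and 0 adjusted over the list alone). These 5 lists, in the order named, gave adjusted p = 0.00302, 4.45e-04, 0.155, 0.658 and 0.902 (preset). With an estimated correlation adjusted p was 0.638, 0.435, 0.826, 0.936 and 0.978.

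Most genes of the cell cycle list fell. In the cell cycle list, 0 of 25 members rose and 22 fell (0 and 23 adjusted over the list alone), with a median of -0.74. Cell cycle genes gave adjusted p = 2.66e-31 (preset) and adjusted p = 0.0950 with an estimated correlation. Ccnb2, a mitotic cyclin, fell by 1.45 ± 0.14, the spindle protein gene Nusap1 by 1.14 ± 0.13, Cdc20, an activator of the anaphase-promoting complex, by 1.01 ± 0.12 and the spindle checkpoint gene Bub1b by 0.74 ± 0.080. In the crypt stem cell and Wnt list, 1 of 18 members rose and 8 fell (3 and 11 adjusted over the list alone). Crypt stem cell and Wnt genes gave adjusted p = 1.94e-04 (preset) and adjusted p = 0.336 with an estimated correlation. Axin2, a target and brake of Wnt signalling, fell by 0.98 ± 0.10, Rnf43, which removes Wnt receptors, by 0.85 ± 0.13, Ephb3 by 0.58 ± 0.10 and the stem cell factor gene Ascl2 by 0.41 ± 0.069, while Nkd1, another Wnt antagonist, rose by 0.60 ± 0.11. In the wound healing and epithelial repair list, 7 of 22 members rose and 0 fell (8 and 0 adjusted over the list alone). Wound healing and epithelial repair genes gave adjusted p = 0.00134 (preset) and adjusted p = 0.355 with an estimated correlation. Anxa1, an annexin that limits inflammation, rose by 0.89 ± 0.17, Itga3 by 0.53 ± 0.14 and the trefoil gene Tff3 by 0.15 ± 0.038. Tff3 lost its call under quantile normalization (0.066) and median centring (0.15), and Itga3 with array weights (0.15), without the 8 narrow arrays (0.19) and with only the 2 groups compared (0.55).

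Epithelial lineages moved in both directions. In the goblet cell list, 9 of 18 members rose and 2 fell (9 and 3 adjusted over the list alone). The mucin genes Muc2 and Muc13 rose by 0.47 ± 0.082 and 0.55 ± 0.076 and Spink4 by 0.35 ± 0.055, while the mucin gene Muc4 fell by 0.39 ± 0.11. In the enteroendocrine and tuft cell list, 10 of 18 members rose and 0 fell (11 and 0 adjusted over the list alone), with Gcg, the proglucagon gene, rising by 1.53 ± 0.17, the granule genes Chga and Chgb by 0.94 ± 0.12 and 0.77 ± 0.092 and the peptide YY gene Pyy by 0.73 ± 0.10. In the absorptive colonocyte list, 6 of 29 members rose and 4 fell (6 and 5 adjusted over the list alone): Clca4a rose by 1.28 ± 0.21 and Lypd8 by 0.22 ± 0.035, and the water channel gene Aqp8 fell by 1.13 ± 0.22. In the tight junction and barrier list, 2 of 22 members rose and 2 fell (3 and 2 adjusted over the list alone). The list's median of 0.11 and mean of -0.0041 differed in sign, Cldn8 rose by 1.28 ± 0.20, and Cldn15 fell by 0.52 ± 0.11 beside Cldn2. In the squamous epithelium list, markers of the stratified lining of the anus and skin, 0 of 23 members rose and 0 fell (0 and 0 adjusted over the list alone). These 5 lists, in the order named, gave adjusted p = 9.45e-05, 1.35e-08, 0.446, 0.821 and 0.854 (preset). With an estimated correlation adjusted p was 0.332, 0.0800, 0.911, 0.986 and 0.986.

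Lists of muscle, matrix, vessel, nerve and fat genes were tested next. In the smooth muscle list, 15 of 17 members rose and 0 fell (15 and 0 adjusted over the list alone), with the heat shock gene Hspb7 rising by 0.99 ± 0.16, the desmin gene Des by 0.81 ± 0.12, the calponin gene Cnn1 by 0.69 ± 0.10 and Tagln by 0.39 ± 0.067. In the fibroblast and matrix list, 13 of 22 members rose and 0 fell (17 and 1 adjusted over the list alone). Thbs1, a matrix glycoprotein gene, rose by 1.57 ± 0.28, Tnc by 0.86 ± 0.18, the growth factor receptor gene Pdgfra by 0.77 ± 0.12 and the fibronectin gene Fn1 by 0.69 ± 0.12. For protease and tissue remodelling genes, 10 of 15 members rose and 0 fell (13 and 0 adjusted over the list alone), including the matrix metalloproteinase genes Mmp14 and Mmp2 by 0.96 ± 0.17 and 0.87 ± 0.17 and the cathepsin gene Ctsk by 0.87 ± 0.15. In the endothelial and lymphatic list, 10 of 16 members rose and 0 fell (11 and 0 adjusted over the list alone), with the junction genes Cdh5 and Pecam1 rising by 0.79 ± 0.15 and 0.67 ± 0.091 and the angiopoietin receptor gene Tek by 0.72 ± 0.11. In the enteric neuron and glia list, 11 of 17 members rose and 1 fell (14 and 1 adjusted over the list alone), with the peripherin gene Prph rising by 0.83 ± 0.13, the synaptic gene Snap25 by 0.51 ± 0.076, the nitric oxide synthase gene Nos1 by 0.42 ± 0.067 and the adhesion gene L1cam falling by 0.64 ± 0.094. In the adipocyte list, 2 of 10 members rose and 0 fell (3 and 0 adjusted over the list alone), with Fabp4, a fatty acid binding protein gene, rising by 0.71 ± 0.16. Cidec and Adipoq of that list, at 1.04 ± 0.39 and 1.02 ± 0.52, did not pass (limma adjusted p = 0.0831 and 0.268), though Cidec passed without scrambled replicate 3 (1.25, limma adjusted p = 0.0382). These 6 lists, in the order named, gave adjusted p = 9.6e-12, 6.41e-09, 1.07e-09, 1.07e-09, 6.95e-09 and 0.0267 (preset). With an estimated correlation adjusted p was 0.205, 0.272, 0.172, 0.134, 0.134 and 0.571.

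Metabolic and stress lists closed the comparison. In the xenobiotic and steroid metabolism list, 0 of 27 members rose and 8 fell (0 and 10 adjusted over the list alone). The sulfotransferase gene Sult1a1 fell by 1.21 ± 0.16, Cyp2d26 by 0.96 ± 0.12 and the glutathione transferase genes Gstm3 and Gstm1 by 0.81 ± 0.080 and 0.73 ± 0.088. In the hypoxia and glycolysis list, 9 of 19 members rose and 0 fell (9 and 0 adjusted over the list alone), with the hexokinase gene Hk2 rising by 1.22 ± 0.26, the vasodilator gene Adm by 1.07 ± 0.23 and the collagen hydroxylase gene P4ha1 by 0.73 ± 0.14; its median was -0.040 in the first amplification batch alone. In the endoplasmic reticulum stress list, 8 of 19 members rose and 0 fell (11 and 0 adjusted over the list alone), with the chaperone genes Hspa5 and Calr rising by 0.60 ± 0.10 and 0.43 ± 0.075. For fatty acid oxidation and ketogenesis, 1 of 20 members rose and 1 fell (1 and 2 adjusted over the list alone), the risen one being the dehydrogenase gene Acadl (0.67 ± 0.18). In the oxidative phosphorylation list, 1 of 25 members rose and 0 fell (0 and 0 adjusted over the list alone). In the housekeeping list, 3 of 10 members rose and 0 fell (3 and 1 adjusted over the list alone), with Actb at 0.22 ± 0.032, higher also under quantile normalization and median centring, which put the median change of all probe sets at -0.015 and -0.023 against -0.027. In the male and female sex marker list, 0 of 4 members rose and 0 fell (0 and 0 adjusted over the list alone). These 7 lists, in the order named, gave adjusted p = 5.55e-07, 1.72e-04, 1.15e-06, 0.478, 0.927, 0.371 and 0.690 (preset). With an estimated correlation adjusted p was 0.254, 0.535, 0.373, 0.920, 0.998, 0.834 and 0.887.

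**Figure D2:**
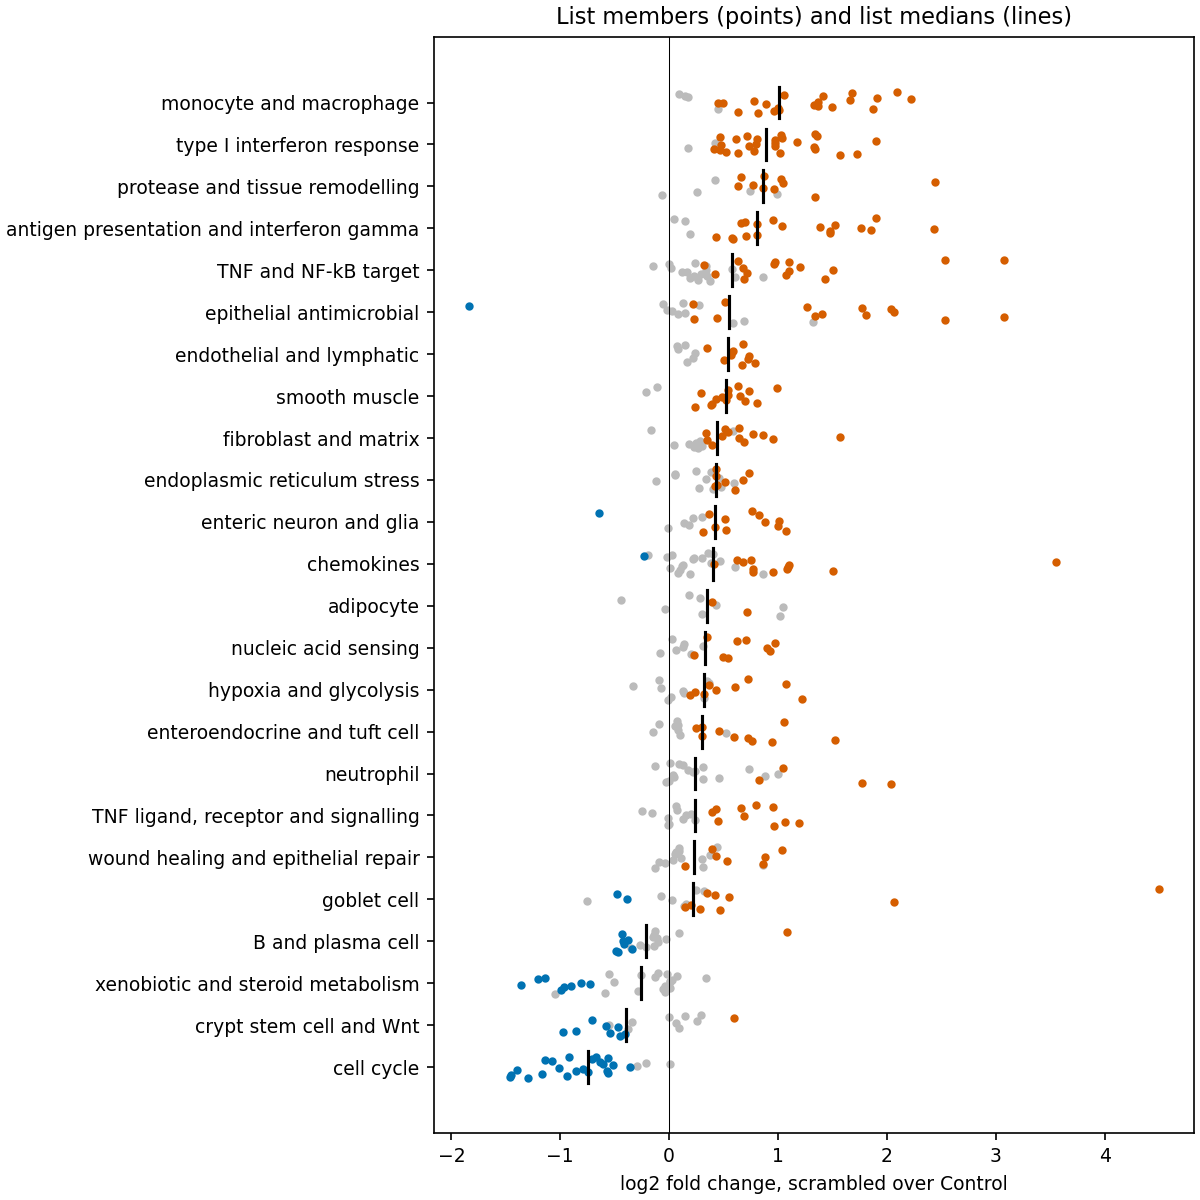
Log2 fold change of scrambled over Control (horizontal axis) for each measured member of the 24 gene lists past the preset test (points), with a line at each list's median; coloured points passed an adjusted p of 0.05 and grey points did not. The monocyte and macrophage list has the highest median, 1.01, and the cell cycle list the lowest, -0.74.

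A further 7 genes named by the rule had calls lost under settings other than single batches. Their values over all arrays were -0.48 ± 0.14 for the goblet cell stress sensor gene Ern2, 0.39 ± 0.12 for the hormone-sensitive lipase gene Lipe, -0.23 ± 0.069 for the chemokine gene Ccl25, 0.16 ± 0.045 for the claudin gene Cldn7, -0.50 ± 0.16 for the short-chain acyl-CoA dehydrogenase gene Acads, 0.29 ± 0.091 for the cytochrome c gene Cycs and 0.36 ± 0.11 for the glucuronidase gene Gusb, with adjusted p values from 0.0179 to 0.0300. Calls were lost, with the direction kept, without Control replicate 1 for Ccl25 (-0.20) and Acads (-0.46), Control replicate 2 for Acads (-0.47), Control replicate 3 for Ern2 (-0.44) and Acads (-0.46), Control replicate 4 for Cycs (0.26) and Gusb (0.29). They were lost without Control replicate 5 for Cycs (0.28), Control replicate 7 for Ern2 (-0.41) and Acads (-0.43), Control replicate 8 for Ccl25 (-0.20), Cycs (0.26) and Gusb (0.30), Control replicate 9 for Acads (-0.48). They were lost without scrambled replicate 1 for Ern2 (-0.42), Ccl25 (-0.21), Acads (-0.47) and Cycs (0.28), scrambled replicate 2 for Ern2 (-0.41), Lipe (0.32), Acads (-0.46), Cycs (0.24) and Gusb (0.35), scrambled replicate 3 for Ern2 (-0.46), Cldn7 (0.14), Acads (-0.47) and Cycs (0.27), scrambled replicate 4 for Lipe (0.34) and Ccl25 (-0.21). They were lost without scrambled replicate 5 for Acads (-0.49), scrambled replicate 6 for Ern2 (-0.44), Acads (-0.49) and Gusb (0.34), scrambled replicate 7 for Cycs (0.28). They were also lost with array weights for Ccl25 (-0.083), Cldn7 (0.073) and Gusb (0.17), without the 8 narrow arrays for Lipe (0.30), Ccl25 (-0.14), Cldn7 (0.091) and Gusb (0.11). They were lost with the replicate number as a block in place of the batch terms for Lipe (0.35), Cycs (0.28) and Gusb (0.31), with median centring for Ern2 (-0.47), Cldn7 (0.16), Acads (-0.50), Cycs (0.30) and Gusb (0.36) and with only the 2 groups compared for Ern2 (-0.47), Lipe (0.39), Ccl25 (-0.23), Cldn7 (0.16), Acads (-0.49) and Gusb (0.36). In the last, calls were lost too for Muc4 (-0.38), Il1rn (0.40), Acadl (0.69) and Ms4a1 (-0.46).

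Tnf, the gene the siRNAs address, was 1.95-fold higher in scrambled than in Control (0.96 ± 0.15 log2, SE, limma adjusted p = 1.83e-05), a call lost in the third amplification batch (0.67, limma adjusted p = 0.469, 3 arrays each). Its mean log2 level was 7.95 ± 0.319 in Control (SD, n = 9), 8.89 ± 0.448 in scrambled (n = 7), 9.10 ± 0.281 with siTNF (n = 6), 8.79 ± 0.250 with siTNF-OMe (n = 6) and 8.69 ± 0.195 with siTNF-OMe-P (n = 8). Against scrambled, Tnf differed by 0.19 (-0.14 to 0.52) log2 with siTNF, -0.12 (-0.46 to 0.21) with siTNF-OMe and -0.23 (-0.54 to 0.085) with siTNF-OMe-P, where the ranges are 95% intervals. No one of these passed (adjusted p = 0.9999, 0.9999 and 0.9998; unadjusted p = 0.258, 0.449 and 0.149 in limma). Between the TNF siRNAs the difference was -0.31 (-0.66 to 0.032) for siTNF-OMe over siTNF, -0.41 (-0.74 to -0.091) for siTNF-OMe-P over siTNF (limma unadjusted p = 0.0137, adjusted p = 0.974) and -0.10 (-0.42 to 0.22) for siTNF-OMe-P over siTNF-OMe. Within amplification batches the sign turned for siTNF over scrambled (-0.35 in the first), siTNF-OMe over siTNF (0.058 in the first), and siTNF-OMe and siTNF-OMe-P over scrambled (0.30 and 0.067 in the third); with array weights siTNF over scrambled was -0.086. The array has 1 Tnf probe set (10450501; the gene lies on chromosome 17 from 35199367 to 35202007 in GRCm38) and the position the siRNAs target is not given in the sources used here.

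**Figure D3:**
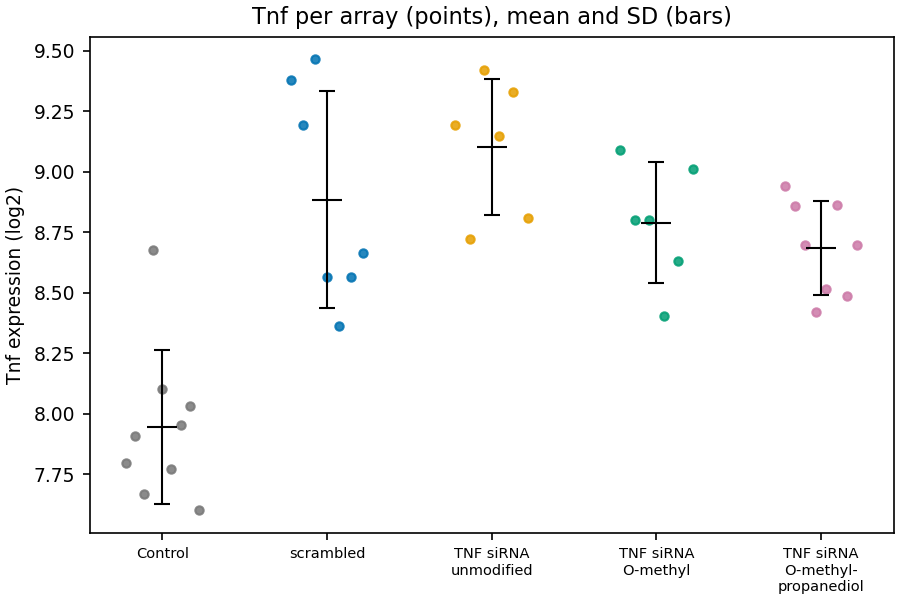
Tnf expression (log2) of each array in the 5 groups, with points for arrays and bars for the mean and SD. The group means run from 7.95 in Control to 9.10 with siTNF.

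The comparison of siTNF with scrambled asks what the unmodified TNF siRNA changed. No probe set passed in limma: 0 were called, and 311 had an unadjusted p under 0.05 where 1442.6 are expected by chance. The 5 genes with the smallest p, none of which passed, were Sgk1, a glucocorticoid-induced kinase gene, at 1.18 ± 0.31 log2 (SE, n = 6 and 7), Gm8995 at -0.43 ± 0.12, the keratin gene Krt23 at 0.78 ± 0.23, Nipal1 at 0.38 ± 0.11 and Fam43a at 0.53 ± 0.16. In the antigen presentation and interferon gamma list, 1 of 21 members were above 0, with a median of -0.27; Psmb9 stood at -0.35 ± 0.15 and the class II regulator gene Ciita at -0.22 ± 0.092. For type I interferon response genes, 0 of 28 members were above 0, with a median of -0.16, with Parp14 at -0.43 ± 0.21 and Herc6 at -0.35 ± 0.21, the latter 0.21 in the second hybridization batch. Of the TNF and NF-kB targets, 27 of 33 members were above 0, with a median of 0.18, with the inhibitor genes Nfkbia and Tnfaip3 at 0.60 ± 0.21 and 0.29 ± 0.13. In the T and NK cell list, 2 of 23 members were above 0, with a median of -0.052, with Cd3g at -0.21 ± 0.12 and the granzyme gene Gzmb at -0.23 ± 0.15. In the neutrophil list, 17 of 21 members were above 0, with a median of 0.13, with Il1r2 at 0.80 ± 0.40 and Ngp at 0.75 ± 0.38. In the order named these 5 lists gave adjusted p = 1.02e-12, 1.9e-10, 2.02e-06, 0.00112 and 0.00140 (preset) and adjusted p = 0.147, 0.373, 0.388, 0.571 and 0.611 with an estimated correlation. The preset test called 10 lists, the estimated correlation and fry 0, and the list means of neutrophil (-0.11), protease (-0.049), chemokine (-0.031) and TNF and NF-kB target genes (-0.0086) turned sign without the 8 narrow arrays. List medians turned sign for antigen presentation (0.060 in hybridization batch 2, 0.074 in amplification batch 3), type I interferon (0.18 in hybridization batch 2, 0.14 in amplification batch 3), TNF target (-0.15 in amplification batch 1) and neutrophil (-0.023 in hybridization batch 2, -0.14 in amplification batch 1, -0.068 in amplification batch 3). Plain differences of list means that 1 array moved over 1.5-fold or turned were antigen presentation (-0.26) without scrambled replicate 1 or 2 (-0.15, -0.14), type I interferon (-0.17) without scrambled replicate 1 or 2 (-0.083, -0.064) or without siTNF replicate 4 (-0.30), TNF target (0.19) without scrambled replicate 2 (0.30) or without siTNF replicate 3 (0.0084), T and NK cell (-0.095) without siTNF replicate 4 (-0.048) and neutrophil (0.16) without scrambled replicate 2 (0.26) or without siTNF replicate 1 or 3 (0.27, -0.16).

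The comparison of siTNF-OMe with scrambled asks the same of the O-methyl siRNA. No probe set passed in limma (0 called, 455 at an unadjusted p under 0.05). Sfrp2, a secreted modulator of Wnt signalling, stood at 0.75 ± 0.18 log2 (SE, n = 6 and 7), the platelet chemokine gene Ppbp at 2.35 ± 0.66, Pde1a at 0.40 ± 0.11, Lor, which encodes the cornified envelope protein loricrin, at 2.38 ± 0.68 and the chemokine receptor gene Cxcr4 at 0.51 ± 0.15. Of the squamous epithelium markers, 22 of 23 members were above 0, with a median of 0.76, with the keratin gene Krt13 at 2.25 ± 0.67. On 4 of 6 siTNF-OMe arrays and 0 of 7 scrambled arrays the mean of these markers was above 8 log2. Of the protease genes, 14 of 15 members were above 0, with a median of 0.42, with the plasminogen activator gene Plat at 0.80 ± 0.28 and Adamts4 at 0.71 ± 0.30. Of the macrophage genes, 23 of 25 members were above 0, with a median of 0.21, with Cd68 at 0.31 ± 0.13 and Clec4n at 0.39 ± 0.17. For the fibroblast and matrix list, 20 of 22 members were above 0, with a median of 0.16, with Timp1, an inhibitor of metalloproteinases, at 0.77 ± 0.32 and the decorin gene Dcn at 0.31 ± 0.14. For endothelial genes, 15 of 16 members were above 0, with a median of 0.17, with Emcn at 0.36 ± 0.15 and Esam at 0.29 ± 0.12. In the order named these 5 lists gave adjusted p = 1.41e-31, 3.37e-14, 6.03e-12, 9.35e-12 and 7.39e-09 (preset) and adjusted p = 0.0800, 0.103, 0.163, 0.172 and 0.147 with an estimated correlation. The preset test called 21 lists, and the estimated correlation and fry called 0. List medians turned sign for protease (-0.061 in amplification batch 1), macrophage (-0.10 in amplification batch 1) and endothelial and lymphatic (-0.046 in amplification batch 1).

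The comparison of siTNF-OMe-P with scrambled asks the same of the O-methyl-propanediol siRNA. Again 0 probe sets passed in limma, with 836 at an unadjusted p under 0.05. Zdbf2 stood at 0.24 ± 0.057 log2 (SE, n = 8 and 7), Mir380 at 0.22 ± 0.055, Tmem267 at 0.52 ± 0.13, Pde1a at 0.41 ± 0.11 and Ly75, an endocytic receptor gene of dendritic cells, at -0.39 ± 0.10. Zdbf2 passed with median centring (0.24) and with array SD as a covariate (0.23). With array weights Zdbf2 (0.22), Mir380 (0.25), Pde1a (0.40) and Ly75 (-0.36) passed, and without Control and with array SD as a covariate Zdbf2 (0.23), Mir380 (0.21), Tmem267 (0.50) and Ly75 (-0.37). For the squamous epithelium markers, 22 of 23 members were above 0, with a median of 0.65, with the basal keratin genes Krt5 and Krt14 at 2.42 ± 0.72 and 1.65 ± 0.57; the mean of the 23 markers was above 8 log2 on 3 of 8 siTNF-OMe-P arrays. In the antigen presentation and interferon gamma list, 0 of 21 members were above 0, with a median of -0.26, with Tap2 at -0.38 ± 0.12 and Psmb9 at -0.31 ± 0.14. Among absorptive colonocyte genes, 4 of 29 members were above 0, with a median of -0.17, with the fatty acid transporter gene Slc5a8 at -0.69 ± 0.21, which passed with array weights (-0.65), and Hsd11b2 at -0.56 ± 0.20. In the type I interferon response list, 0 of 28 members were above 0, with a median of -0.20, with Parp14 at -0.42 ± 0.20 and Oas1a at -0.21 ± 0.10. In the goblet cell list, 2 of 18 members were above 0, with a median of -0.16, with Muc2 at -0.26 ± 0.085 and Capn9 at -0.38 ± 0.14. In the order named these 5 lists gave adjusted p = 1.9e-19, 6.95e-09, 7.89e-09, 1.27e-08 and 9.25e-08 (preset) and adjusted p = 0.166, 0.230, 0.336, 0.435 and 0.156 with an estimated correlation. The preset test called 19 lists and the estimated correlation and fry 0. List medians turned sign for antigen presentation (0.10 in amplification batch 3) and type I interferon (0.27 in amplification batch 3). Plain differences of list means that 1 array moved over 1.5-fold or turned were antigen presentation (-0.24) without scrambled replicate 1 or 2 (-0.13, -0.13) and type I interferon (-0.16) without scrambled replicate 1, 2 or 7 (-0.070, -0.050, -0.24) or without siTNF-OMe-P replicate 2 (-0.090).

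The O-methyl siRNA was set against the unmodified one next, a difference of chemistry on the same target gene. Limma called 0 probe sets and 494 had an unadjusted p under 0.05; the median 95% interval of a probe set reached 0.25 log2 to each side. Fabp5, a fatty acid binding protein gene of keratinocytes, stood at 0.77 ± 0.18 log2 (SE, n = 6 each), the apelin receptor gene Aplnr at 0.56 ± 0.14, Slc35g1 at -0.47 ± 0.13, Krtap5-2 at 0.86 ± 0.25 and 9030619P08Rik at -0.53 ± 0.15. In the squamous epithelium list, 23 of 23 members were above 0, with a median of 0.77, with Lor at 2.22 ± 0.71 and the keratin gene Krt1 at 2.03 ± 0.67. Among macrophage genes, 21 of 25 members were above 0, with a median of 0.20, with Itgax at 0.24 ± 0.11 and Cd68 at 0.27 ± 0.14. For fibroblast and matrix genes, 19 of 22 members were above 0, with a median of 0.16, with the collagen gene Col3a1 at 0.39 ± 0.16 and Timp1 at 0.62 ± 0.33. Of the protease genes, 14 of 15 members were above 0, with a median of 0.22, with Mmp10 at 1.03 ± 0.42 and Mmp3 at 0.79 ± 0.45. In the B and plasma cell list, 17 of 19 members were above 0, with a median of 0.079, with Ly6d at 0.58 ± 0.34 and Mzb1 at 0.16 ± 0.10, which was -0.021 in the first hybridization batch. In the order named these 5 lists gave adjusted p = 6.53e-29, 7.39e-09, 6.86e-07, 2.23e-06 and 3.18e-05 (preset) and adjusted p = 0.0950, 0.230, 0.366, 0.332 and 0.351 with an estimated correlation. The preset test called 21 lists, and the estimated correlation and fry called 0. List medians turned sign for protease (-0.072 in amplification batch 2). Plain differences of list means that 1 array moved over 1.5-fold or turned were macrophage (0.20) without siTNF replicate 3 (0.30), protease (0.35) without siTNF replicate 3 (0.56) and B and plasma cell (0.12) without siTNF replicate 4 (0.058).

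Set against the unmodified siRNA, the O-methyl-propanediol one went with a higher median of squamous genes and lower medians of colonocyte, goblet cell and tight junction genes, none past the estimated-correlation test. It gave 0 called probe sets in limma and 1002 at an unadjusted p under 0.05, with a median 95% interval of 0.24 log2 to each side. Cstdc6, a cystatin family gene, stood at 0.42 ± 0.10 log2 (SE, n = 8 and 6), Cpn2 at -0.37 ± 0.089, the phospholipase gene Pla2g4f at -0.37 ± 0.088, 9030619P08Rik at -0.60 ± 0.14 and Stmn1, a regulator of microtubules, at 0.29 ± 0.072. Cpn2 and Stmn1 passed with quantile normalization (-0.39 and 0.35) and with array SD as a covariate with Control (-0.41 and 0.33) or without it (-0.38 and 0.34). In the squamous epithelium list, 22 of 23 members were above 0, with a median of 0.72, with Krt13 at 1.55 ± 0.65 and Sprr3 at 0.69 ± 0.27. Of the absorptive colonocyte genes, 2 of 29 members were above 0, with a median of -0.28, with the chloride-bicarbonate exchanger gene Slc26a3 at -0.65 ± 0.22 and Sult1a1 at -0.48 ± 0.18. In the goblet cell list, 1 of 18 members were above 0, with a median of -0.15, with Muc2 at -0.29 ± 0.089 and the goblet cell factor gene Spdef at -0.35 ± 0.13. Among tight junction and barrier genes, 3 of 22 members were above 0, with a median of -0.17, with the cingulin gene Cgn at -0.32 ± 0.10 and Cldn7 at -0.11 ± 0.049. For the B and plasma cell list, 18 of 19 members were above 0, with a median of 0.14, with Ly6d at 0.91 ± 0.31 and Cd79b at 0.25 ± 0.12, which was -0.14 in the first hybridization batch. In the order named these 5 lists gave adjusted p = 2.38e-15, 3.54e-10, 8.21e-07, 2.25e-06 and 3.76e-06 (preset) and adjusted p = 0.214, 0.272, 0.172, 0.437 and 0.278 with an estimated correlation. The preset test called 17 lists, and the estimated correlation and fry called 0. List medians turned sign for colonocyte (0.0062 in amplification batch 2) and B and plasma cell (-0.12 in hybridization batch 1). Plain differences of list means that 1 array moved over 1.5-fold or turned were squamous (0.78) without siTNF-OMe-P replicate 1 (0.51) and B and plasma cell (0.16) without siTNF replicate 4 (0.10).

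Between siTNF-OMe-P and siTNF-OMe, epithelial antimicrobial genes were the 1 list past the estimated-correlation test, lower with siTNF-OMe-P. In all, 0 probe sets were called in limma and 74 had an unadjusted p under 0.05. Zdbf2 stood at 0.19 ± 0.059 log2 (SE, n = 8 and 6), Rpph1, the RNA component of ribonuclease P, at 0.18 ± 0.063, the homeobox gene Hoxa2 at -0.12 ± 0.043, Gm10229 at -0.89 ± 0.34 and 2210407C18Rik at -0.71 ± 0.27, the last being 0.013 in the first hybridization batch. In the epithelial antimicrobial list, 3 of 24 members were above 0, with a median of -0.20, and the list passed with the preset (adjusted p = 9.18e-10) and with an estimated correlation (adjusted p = 0.00182) but not in fry (adjusted p = 0.117). Of its members Duox2, a hydrogen peroxide producing oxidase gene, stood at -0.36 ± 0.19 and Pigr, the receptor that carries antibody into the lumen, at -0.17 ± 0.083. Among macrophage genes, 2 of 25 members were above 0, with a median of -0.16, with Itgax at -0.22 ± 0.11 and Cd14 at -0.43 ± 0.28. In the nucleic acid sensing list, 0 of 16 members were above 0, with a median of -0.10, with Tlr7 at -0.23 ± 0.12 and Tlr8 at -0.10 ± 0.065, the latter 0.050 in the first hybridization batch. For absorptive colonocyte genes, 6 of 29 members were above 0, with a median of -0.057, with Cyp2c55 at -0.85 ± 0.44 and Clca4a at -0.36 ± 0.23. For TNF and NF-kB targets, 5 of 33 members were above 0, with a median of -0.080, with Rel at -0.38 ± 0.23 and Saa3 at -0.77 ± 0.49. In the order named the other 4 lists gave adjusted p = 1.25e-12, 2.2e-07, 1.87e-06 and 7.87e-06 (preset) and adjusted p = 0.151, 0.172, 0.435 and 0.435 with an estimated correlation. The preset test called 19 lists, the estimated correlation 1 and fry 0. List medians turned sign for nucleic acid sensing (0.053 in amplification batch 2) and TNF target (0.020 in amplification batch 2). Plain differences of list means that 1 array moved over 1.5-fold or turned were macrophage (-0.15) without siTNF-OMe-P replicate 7 (-0.10), colonocyte (-0.080) without siTNF-OMe replicate 1, 4 or 5 (-0.051, -0.050, -0.14) or without siTNF-OMe-P replicate 3, 4, 5 or 8 (-0.048, -0.12, -0.043, -0.033) and TNF target (-0.12) without siTNF-OMe replicate 3 (-0.077) or without siTNF-OMe-P replicate 3 or 7 (-0.19, -0.042).

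Beyond the 5 lists of smallest p named for each comparison, 5, 16, 14, 16, 12 and 14 more passed the preset test in the 6 comparisons in the order given, with adjusted p from 0.166 to 0.802 with an estimated correlation. None of these passed with an estimated correlation or in fry, and in simulated data with 1 shifted list the preset test called 48.9% and 39.4% of the unshifted lists in the 2 comparisons simulated.

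Each TNF siRNA group also differed from Control. Tnf was higher than in Control by 1.15 ± 0.15 log2 with siTNF (SE, limma adjusted p = 2.12e-06), 0.84 ± 0.15 with siTNF-OMe (limma adjusted p = 1.48e-04) and 0.74 ± 0.14 with siTNF-OMe-P (limma adjusted p = 2.54e-04). These calls were lost in amplification batch 3 for all 3 (1.21, 0.97 and 0.74, limma adjusted p = 0.0742, 0.116 and 0.357), and for siTNF-OMe and siTNF-OMe-P in amplification batch 2 (0.65 and 0.62, limma adjusted p = 0.130 and 0.0945) and hybridization batch 1 (0.84 and 0.71, limma adjusted p = 0.0785 and 0.139). MPO activity exceeded Control by 0.264 (0.116 to 0.431), 0.568 (0.333 to 0.841) and 0.304 (0.122 to 0.507) U per mg in the same order, with exact permutation adjusted p values of 0.00180, 6.66e-04 and 0.00411. Colon length differed from Control by -1.84 (-2.27 to -1.40), -1.74 (-2.06 to -1.43) and -1.31 (-1.63 to -0.988), and the ratio by 0.676 (0.512 to 0.840), 0.706 (0.569 to 0.838) and 0.381 (0.199 to 0.555), all with an exact permutation adjusted p of 0.00292 or less. Limma called 3982 probe sets for siTNF (2624 up, 1358 down), 4275 for siTNF-OMe (2599 up, 1676 down) and 4596 for siTNF-OMe-P (2698 up, 1898 down). Without the 8 narrow arrays the counts were 6021, 15575 and 13845. Most calls fell for siTNF without those arrays (2487 up and 3534 down) and with array weights (3166 up and 4758 down), for siTNF-OMe with array SD as a covariate (4125 up and 4469 down), for all 3 within hybridization batch 1 (333 up and 455 down for siTNF), and for siTNF and siTNF-OMe within amplification batch 1 (621 up and 1335 down for siTNF).

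Whether the TNF siRNAs moved the scrambled-to-Control difference back was read as a slope across the probe sets called for scrambled over Control in a split (median 335), where -1 would be a full return and 0 none. The slope was 0.062 for siTNF (range -0.075 to 0.222 over 70 splits of the scrambled arrays), 0.132 for siTNF-OMe (-0.019 to 0.323) and 0.056 for siTNF-OMe-P (-0.107 to 0.256), and it was negative in 10, 2 and 16 of the 70 splits. Genes are not independent replicates, so these slopes carry no p. With the scrambled arrays unsplit, so that they entered both differences, the slopes over the 3384 called probe sets were 0.0215, 0.118 and 0.0347. For these unsplit slopes, simulated data with no effect gave means of -0.011, 0.0013 and -0.0073, with ranges of -0.176 to 0.176, -0.171 to 0.159 and -0.156 to 0.153. The split slopes had no such simulation, so these ranges do not apply to them. No probe set passed against scrambled, so the called sets shared 0. At an unadjusted p under 0.01, siTNF and siTNF-OMe shared 1 probe set in the same direction, siTNF and siTNF-OMe-P 4, and siTNF-OMe and siTNF-OMe-P 18. Simulations in which the comparisons share the scrambled arrays and nothing else gave means of 2.78, 2.64 and 3.32 and highest values of 41, 36 and 67.

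Antigen presentation genes followed MPO activity from animal to animal. Over the 27 siRNA-dosed animals, the mean score of the antigen presentation and interferon gamma list had a Pearson r of 0.784 with MPO (permutation p = 2e-05, adjusted p = 7.00e-04 over 35 lists) and a Spearman rho of 0.641 (permutation p = 5.20e-04, adjusted p = 0.0182). Without the 2 animals farthest from the median MPO, scrambled replicate 2 (1.35 U per mg) and siTNF-OMe replicate 1 (1.16), r was 0.669 (permutation adjusted p = 0.0161). With group means removed r was 0.784 (permutation adjusted p = 0.00175), with log2 MPO 0.625, within the hybridization batches 0.895 and 0.469, and within the amplification batches 0.858, 0.743 and 0.729 (6, 12 and 9 animals). The type I interferon response list passed with r (0.586, permutation adjusted p = 0.0313) but not with rho (0.468, 0.0906). Its r was 0.390 without the 2 animals (adjusted p = 0.328), with 0.859 and 0.160 in the hybridization batches. The epithelial antimicrobial list passed with r (0.549, permutation adjusted p = 0.0322) and not with rho (0.371, 0.155). Nor did it without the 2 animals (0.380, 0.328), with 0.636 and 0.457 in the hybridization batches. The chemokine list passed with rho alone (0.579, permutation p = 0.00211, adjusted p = 0.0369; r = 0.489, permutation p = 0.0109, adjusted p = 0.0600). The neutrophil list, whose cells carry MPO, passed with neither r (0.259, permutation adjusted p = 0.419) nor rho (0.454, 0.0906).

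**Figure D4:**
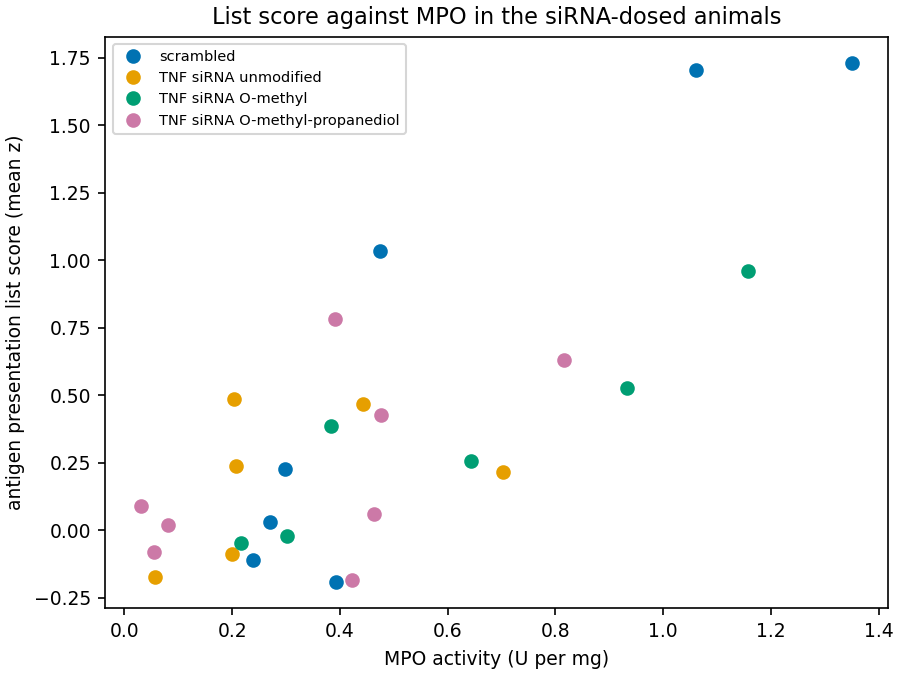
Antigen presentation list score (mean z-score of members) against MPO activity (U per mg) for the 27 siRNA-dosed animals, coloured by group. The score rises with MPO over the 27 animals, with a Pearson r of 0.784.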

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

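The tests in this part were chosen before their results were seen. Of 30 group measures examined for a sample far from the others, 4 had one, where chance gives about 1 in 20. Scrambled replicate 3 had a colon length of 6.7, with the other scrambled animals from 5.8 to 6.1. Control replicate 6 had a weight to length ratio of 2.47 (others 2.03 to 2.21) and a colon weight of 200.0 mg (others 154 to 172), which is 1 animal in 2 linked measures. Tnf on Control replicate 4 was 8.68 log2, with the other Control arrays from 7.60 to 8.10. That array also had the lowest SD of the 36 arrays, 1.55.

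A difference between TNF siRNA groups was found for 3 results. The weight to length ratio with siTNF-OMe-P minus that with siTNF was -0.294 mg per mm, and minus that with siTNF-OMe -0.325. The first did not pass as medians (-0.213), with a recomputed ratio (-0.271) or without siTNF replicate 3 (-0.245) or 6 (-0.265), while the second passed in all. The epithelial antimicrobial list had a mean of -0.21 log2 for siTNF-OMe-P over siTNF-OMe and did not pass in fry (adjusted p = 0.117). No explanation was tested for these, and the 2 siRNAs differ in chemistry by design.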

How the results depend on the processing

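The fits without the arrays of SD under 1.7, with array SD as a covariate and without Control, and the list means with 1 array left out, were chosen after the data were seen, and the other alternatives before. Results were recomputed with 1 choice changed at a time, save that the replicate number as a block replaced both batch terms, and leaving out Control was also joined with array SD as a covariate. Of 366 recomputed counts of called probe sets 306 stayed within 1.5 times, of 70 list counts 57, and 323 of 336 values of Tnf, 6464 of 6630 of the named genes and 529 of 552 of the colon measures kept direction and side of the threshold. Single list shifts did in 961 of 1310, with 341 losing the threshold and 8 the direction. Over the alternatives Tnf in scrambled over Control ran from 0.67 to 1.46 log2. With the block 2931 of the 3384 probe sets called for scrambled over Control kept their call and Tnf was 0.90. Of 64 pairs of arrays of the same number 32 had r above 0.1 (-0.697 to 0.868, median 0.124). Pairs of different numbers were not examined, so whether the numbers pair the arrays cannot be told. What dim signal limits was examined only by leaving dim probe sets out, which changed no count by 1.5 times.

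Within hybridization batch 1, calls were 1031, 788, 1233 and 1411 (scrambled, siTNF, siTNF-OMe and siTNF-OMe-P over Control). There, Mzb1, siTNF-OMe over siTNF was -0.0209, Cd79b, siTNF-OMe-P over siTNF was -0.145, 2210407C18Rik, siTNF-OMe-P over siTNF-OMe was 0.0129, Tlr8, siTNF-OMe-P over siTNF-OMe was 0.0497, Tnf, siTNF-OMe over Control was 0.842, Tnf, siTNF-OMe-P over Control was 0.711. Within hybridization batch 2, calls were 1048, 1584, 2104 and 2215 in the same order. There, Herc6, siTNF over scrambled was 0.211. Within amplification batch 1, calls were 1181 (scrambled over Control), 1 (siTNF over scrambled), 27 (siTNF-OMe over scrambled), 29 (siTNF-OMe-P over scrambled), 27 (siTNF-OMe over siTNF), 63 (siTNF-OMe-P over siTNF), 61 (siTNF-OMe-P over siTNF-OMe), 1956 (siTNF over Control), 2309 (siTNF-OMe over Control), 8804 (siTNF-OMe-P over Control). There, Tnf, siTNF over scrambled was -0.350, Tnf, siTNF-OMe over siTNF was 0.0584. Within amplification batch 2, calls were 17 (siTNF over scrambled), 9 (siTNF-OMe over siTNF), 16 (siTNF-OMe-P over siTNF), 2187 (siTNF-OMe over Control), 3018 (siTNF-OMe-P over Control). There, Tnf, siTNF-OMe over Control was 0.646, Tnf, siTNF-OMe-P over Control was 0.619. Within amplification batch 3, calls were 54, 110, 202 and 58 in the order of hybridization batch 1. There, Tnf, scrambled over Control was 0.669, Tnf, siTNF-OMe over scrambled was 0.298, Tnf, siTNF-OMe-P over scrambled was 0.0667, Tnf, siTNF over Control was 1.21, Tnf, siTNF-OMe over Control was 0.967, Tnf, siTNF-OMe-P over Control was 0.736. Each value of Tnf over Control given here had lost its call. Batches hold fewer arrays, which can lower a count, and a group with 1 array was assumed to vary like the others; for the counts that rose and the signs that turned the cause was not tested.

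With only the 2 groups compared, calls were 1731, 1321, 2768 and 2806 (scrambled, siTNF, siTNF-OMe and siTNF-OMe-P over Control). With quantile normalization, calls were 4 (siTNF-OMe-P over siTNF). With median centring, calls were 1 (siTNF-OMe-P over scrambled). With array weights, calls were 16262 (scrambled over Control), 198 (siTNF-OMe-P over scrambled), 1 (siTNF-OMe over siTNF), 7924 (siTNF over Control), 13758 (siTNF-OMe over Control), 13579 (siTNF-OMe-P over Control). There, Tnf, siTNF over scrambled was -0.0860. With a log2 change of at least 1, calls were 315, 373, 527 and 423 (scrambled, siTNF, siTNF-OMe and siTNF-OMe-P over Control). With a log2 change of at least 0.5, calls were 1438, 1727, 2063 and 1945 in the same order. Without the arrays of SD under 1.7, calls were 14417, 6021, 15575 and 13845 in the same order. There, neutrophil, siTNF over scrambled was -0.112, protease and tissue remodelling, siTNF over scrambled was -0.0485, TNF and NF-kB target, siTNF over scrambled was -0.00857, chemokines, siTNF over scrambled was -0.0311, type I interferon response, siTNF-OMe over siTNF was -0.00651, xenobiotic and steroid metabolism, siTNF-OMe-P over siTNF-OMe was 0.0123. With array SD as covariate, calls were 7372 (scrambled over Control), 8 (siTNF-OMe-P over scrambled), 1 (siTNF-OMe over siTNF), 8 (siTNF-OMe-P over siTNF), 7594 (siTNF over Control), 8594 (siTNF-OMe over Control), 9400 (siTNF-OMe-P over Control). Without the Control arrays, array SD as covariate, calls were 30 (siTNF-OMe-P over scrambled), 28 (siTNF-OMe-P over siTNF). With estimated correlation, shifted lists were 2 (scrambled over Control), 0 (each comparison of siRNA groups but the last), 1 (siTNF-OMe-P over siTNF-OMe). With fry, shifted lists were 0 (each comparison of siRNA groups). With replicate block in place of batch terms, crypt stem cell and Wnt, siTNF-OMe-P over siTNF-OMe was 0.00846, tight junction and barrier, siTNF-OMe-P over siTNF-OMe was 0.00343. With log2 of MPO activity and ratio, MPO activity, siTNF-OMe-P over siTNF was -0.113. With difference in medians, MPO activity, siTNF-OMe-P over scrambled was 0.0140, weight to length ratio, siTNF-OMe-P over siTNF was -0.213. Recomputed from weight and length, that ratio difference was -0.271. With permutation within hybridization batches, colon length, siTNF-OMe-P over siTNF-OMe was 0.429. With log2 MPO, or without the 2 animals farthest from the median MPO, the count of lists related to MPO was 1. With unadjusted p under 0.01, the overlap of comparisons over scrambled was 1 (siTNF and siTNF-OMe), 4 (siTNF and siTNF-OMe-P) and 18 (siTNF-OMe and siTNF-OMe-P). For these the cause was not tested, apart from the larger minimum change, which passes fewer probe sets by construction.

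Leaving out 1 array or animal at a time gave these lowest and highest values where a call or sign changed: in scrambled over Control Ern2 -0.599 to -0.405, Lipe 0.322 to 0.463, Ccl25 -0.265 to -0.196, Cldn7 0.124 to 0.181, Acads -0.624 to -0.427, Cycs 0.237 to 0.329, Gusb 0.291 to 0.415, Cidec 0.903 to 1.25, MPO activity, siTNF-OMe over scrambled -0.0879 to 0.1502, colon length, siTNF-OMe-P over scrambled 0.186 to 0.396, MPO activity, siTNF-OMe-P over siTNF -0.0274 to 0.120, colon length, siTNF-OMe over siTNF -0.0267 to 0.213, colon length, siTNF-OMe-P over siTNF 0.403 to 0.642, weight to length ratio, siTNF-OMe over siTNF -0.00550 to 0.0801, weight to length ratio, siTNF-OMe-P over siTNF -0.331 to -0.233, colon length, siTNF-OMe-P over siTNF-OMe 0.324 to 0.482. Calls for scrambled over Control ran from 2629 to 3565. The other counts, named genes and colon measures kept direction and side of the threshold.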

Other observations

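Tests chosen after their results were seen were those of array SD as a covariate (its splits included), the share of epithelium, the fits without Control, narrow arrays as the whole cause and the correlation of squamous markers; the others were chosen before. Xist, expressed from the inactive X chromosome of females, ran from 9.74 to 11.2 log2 over the 36 arrays, and the Y-linked gene Eif2s3y from 5.20 to 5.43. The squamous epithelium markers averaged 7.36 log2 in Control, 7.42 in scrambled, 7.53 with siTNF, 8.45 with siTNF-OMe and 8.31 with siTNF-OMe-P, and 0, 0, 1, 4 and 3 arrays were above 8.

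The 3384 probe sets called for scrambled over Control were weighed against 3 technical explanations. Array spread as a trend is argued against, since 100% of them kept direction and threshold with array SD as a covariate. A lower share of epithelium stays open: the lists tested (macrophage minus B cell 1.27 log2, 0.996 to 1.54) were chosen after being seen. They do not measure epithelium. Muscle and vessel genes rose, but so did goblet genes. Narrow arrays are argued against as the whole cause, since 80.3% kept direction and threshold without them (lower 95% bound 52.1, close to the 50 they allow, from leaving out 1 more array at a time, 70.1 to 82.3%), but what they add cannot be told apart from a group effect, with 4 of the 8 in Control: all 3384 kept direction, and for the 667 that lost the threshold the median absolute log2 was 0.381 (SE 0.112) with and 0.146 (SE 0.0896) without them. What Control received, and so a biological explanation, stays open and untested.

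No probe set was called among the siRNA groups, with 311 to 1002 at an unadjusted p under 0.05 in 5 comparisons and 74 for siTNF-OMe-P over siTNF-OMe. Without Control limma also called 0, yet the count at an unadjusted p under 0.05 was higher in all 6 (287 to 4322). With array SD as a covariate 17 were called, and with both changes 58, 30 for siTNF-OMe-P over scrambled and 28 over siTNF, so neither the spread of the Control arrays nor that of all arrays can be told apart from a lack of differences. With array weights 198 were called for siTNF-OMe-P over scrambled (156 up and 42 down), 1 for siTNF-OMe over siTNF and 0 in the other 4. An effect of the siRNA chemistry stays open and untested.

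The squamous list was higher with siTNF-OMe than with scrambled by 1.04 log2 (exact permutation p = 0.00408, not adjusted for its choice among 37 lists; over all lists, adjusted p = 0.0800 with an estimated correlation and 0.221 in fry) and with siTNF-OMe-P by 0.889 (exact permutation p = 0.0542). A batch is argued against, since the siTNF-OMe difference was at least 0.98 in both hybridization batches, although 0.096 in the first amplification batch with 1 array each, and the siTNF-OMe-P difference ran from 0.111 to 2.49 over amplification batches. For narrow arrays the test decides nothing, since they are 1 scrambled and no siTNF-OMe array (101.1% of the difference stayed without it) and at least 98.3% stays without any 1 scrambled array. The 23 markers came and went together within groups (median pairwise r = 0.758, from -0.631 to 0.988), so anal or skin lining in some samples may be the source; Sprr1a is on another list too, and how many the colon itself expresses was not tested. An effect of the modified siRNAs stays open and untested.

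Chance was examined with 100 splits of the arrays into groups of the same sizes, counting those with a result as large, the real one included, with the real and the highest other value in brackets. For probe sets called over Control chance was not excluded: 8 (3384, 19510) for scrambled and 5 (3982, 18562) for siTNF. For siTNF-OMe and siTNF-OMe-P it was 7 (4275, 17037) and 7 (4596, 16318). The 6 comparisons of siRNA groups called 0, which all 100 splits reach, so nothing is tested there (highest other 0, 1, 0, 0, 9601, 48 in the order of the report). Some splits called several times the real count, which points to a structure of the arrays, and the count had a rank correlation of 0.353 with the difference in array SD for scrambled over Control. For shifted lists chance was not excluded either: 13 (24, 29) for scrambled over Control, 91 (10, 24) for siTNF over scrambled, 24 (21, 25) for siTNF-OMe over scrambled, 33 (19, 27) for siTNF-OMe-P over scrambled, 21 (21, 25) for siTNF-OMe over siTNF, 53 (17, 23) for siTNF-OMe-P over siTNF, 18 (19, 27) for siTNF-OMe-P over siTNF-OMe. With array SD as a covariate no other split reached the count over Control: 1 (7372, 900) for scrambled and 1 (7594, 3868) for siTNF. The same held for siTNF-OMe, 1 (8594, 2150), and siTNF-OMe-P, 1 (9400, 6796). No share of splits was adjusted over the 10 comparisons, and 1 is the lowest possible. For siTNF-OMe-P over scrambled, 3 (8, 1495), and siTNF-OMe over siTNF, 2 (1, 1), the share was under 0.05, with few calls. For siTNF-OMe-P over siTNF, 6 (8, 836), chance was not excluded. The other 3 called 0 there, which tests nothing (highest other 835, 3, 46).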
